A study of Mus musculus with 629 samples.

How the data were processed

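Brain cells of mice of 3 Notch3 genotypes, wild-type (WT), heterozygous (Het) and knockout (KO), had been sorted singly into 384-well plates and sequenced with the SMART-seq2 full-length method, in which every read is a PCR copy and no molecular identifier marks the original molecule. The labels gave each cell a genotype, a plate and a cell type: macrophages, microglia or a type named only 7. The table deposited by the authors held whole-number counts, 1 column per cell, for 53546 gene symbols and 92 ERCC spike-in sequences, with no normalisation. The submitters' processing notes named the aligner STAR, without a version. The genome build, the annotation, the counting program and any filter applied to cells before deposit were not given in the sources used here.

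All 629 columns were matched to their labels by name, and no pair of columns was identical. ERCC counts were 1.22% of all counts and were set aside. Counts were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Gene names and overlapping exons were looked up in GENCODE M21, in which 50067 of the symbols were found. No coordinates are given because the authors' build is not known.

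No label named an animal, and each deposited sample was 1 cell. Xist and Y-linked genes showed cells of both sexes in every genotype, so each held more than 1 animal, but cells could not be assigned to animals. A genotype within a cell type was treated as 1 sample: no test between genotypes was run, and no p-value, standard error or number of significant genes is given. Counts were summed over the cells of a genotype and scaled to CPM, the usual unit of counts relative to a summed total, here that of all genes, with an exact Poisson 95% interval. Ratios were formed on CPM + 1. Shares of cells carry an exact (Clopper-Pearson) 95% interval. Both intervals cover counting error only. Reads can be PCR copies of 1 molecule, so the Poisson interval may be too narrow. A count of 0 was given the upper limit that 3 counts would set.

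A gene was called apart in KO when it reached 20 CPM and had a count in 25% of cells, both in the same genotype, when KO lay at least 2-fold above or below both WT and Het, and when every KO plate lay above or below every WT and Het plate. The cells of 1 genotype on 1 plate are called a pool, and pools of at least 10 cells were used, which gave 8 pools per cell type, 2 of KO and 6 of controls. Het was compared with WT by the same rule. As a yardstick, the rule was applied to every other choice of 2 of the 8 pools against the remaining pools summed. For KO, up to 12 genes in each direction with the largest mean of both log2 ratios are named, and for Het against WT up to 5 in each direction by log2 ratio. Predicted genes, pseudogenes, ribosomal protein genes, mitochondrial genes, Xist and Y-linked genes were counted but not named under that rule. Notch3 and the sex-linked genes are named as values. A few genes that these rules take are not printed, and the counts include them.

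The 26 gene lists held 362 genes, all present in the table. They covered the Notch pathway, perivascular macrophage markers, MHC class II and antigen presentation, homeostatic microglia markers, disease-associated microglia genes, interferon response, immediate early and dissociation stress genes, inflammatory cytokines and NF-kB, lysosome, phagocytosis and scavenger receptors, complement, cholesterol and lipid handling, iron and heme handling, growth factors and matrix remodelling, oxidative phosphorylation, cell cycle, sex-linked genes, and markers of mural cells, endothelium, fibroblasts, astrocytes, oligodendrocytes, neurons, monocytes and neutrophils, lymphocytes and dendritic cells. Ribosomal protein genes, without kinases and binding proteins of similar name, and mitochondrial genes were taken by symbol. Members of at least 5 CPM in a genotype entered a list's median log2 ratio, and a list with fewer than 3 such members was given no median. The median was placed among 10000 random lists of the same size matched for expression and given as a percentile, which ranks genes within these cells and is no test between genotypes. Members apart at a 1.5-fold limit are named, and otherwise the 2 members with the highest summed CPM serve as examples. The groups, rules, lists and most alternatives were fixed before the data were examined.

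Alternatives replaced the summed level by the mean of the cells' own CPM or by the mean of pools, the scaling by edgeR 4.0.16 TMM factors or DESeq2 1.42.0 size factors in R 4.3.3, and the pseudocount, floors, detection limit and fold limit by other values. Cells were also thinned to the 10th percentile of depth of their cell type, cells under 50000 counts or 1000 genes were left out, each gene was stripped of its top cell in each pool, each plate was left out in turn, and single plates holding both genotypes were used alone. Leaving Rn18s out of the total, and using plates 056s, 059s and 060s or plates 524s, 529s and 530s alone, were chosen after seeing the data, as was a removal from each macrophage pool of the 10% of cells, and of 5% and 20%, with the highest share of interferon list counts in all counts but Rn18s. The rule was tested on simulated counts with the depth and spread between cells of these data. For macrophages it recovered 26% of genes set 2-fold apart and 76% of those set 4-fold apart, and it called 33 unchanged genes of 5375 measured. A spread between pools of log2 SD 0.774, taken from the observed pools, was then added. It already holds noise between cells and so may overstate the real one. With it the rule recovered 20% and 50% and called 191 unchanged genes. For microglia the corresponding values were 30%, 92% and 47 of 5598 measured genes, and 20%, 52% and 202 with a pool spread of 0.720. The 14 cells of type 7 entered no comparison between genotypes, and Dixon's limits were used only to find extreme cells among them. No doublet caller was run.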

Results

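The deposited table covered 629 single brain cells from mice of 3 Notch3 genotypes on 6 plates. The labels placed 400 cells among macrophages, 215 among microglia and 14 in a type named 7. Macrophages numbered 211 WT, 70 Het and 119 KO cells, and microglia numbered 79 WT, 58 Het and 78 KO cells. Plate 060s held 98 of the KO macrophages and plate 530s 138 of the WT macrophages. Plate 056s supplied 40920487 of the 52229112 gene counts of Het macrophages. Total gene counts per cell had a median of 403199 and ran from 2751 to 2623170, with a median of 3731 genes per cell. Among macrophages the median total was 433896 in WT (2751 to 2339113), 575834 in Het (93086 to 2623170) and 223509 in KO (13779 to 1711183). Among microglia it was 522985 in WT (15376 to 1779150), 526240 in Het (52985 to 2543646) and 399717 in KO (47330 to 1632145). Rn18s, the 18S ribosomal RNA, took 40.4% of all gene counts, and its median share per cell ran from 15.8% on plate 056s to 54.5% on plate 529s. No label named an animal, so cells could not be assigned to animals, each genotype of a cell type was treated as 1 sample, and no test between genotypes was run.

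Notch3, the gene knocked out, was close to absent in all groups. WT macrophages held 77 Notch3 counts, all in 1 of 211 cells, or 0.696 CPM (95% interval 0.549 to 0.870). Those counts can be PCR copies of fewer molecules in that cell, so the interval does not place WT above Het or KO. Het macrophages held 0 counts in 70 cells, which allows a share of up to 4.29% of cells with a count, and KO macrophages held 2 counts in 1 of 119 cells. Each genotype of microglia held 1 count in 1 cell. The genotype labels could not be checked from Notch3, which had 0 counts among 73617059 gene counts of WT macrophages of plate 530s.

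The cell type labels went with marker genes, which is a check of the labels alone because the labels were probably made from the same counts. All 16 perivascular macrophage markers were higher in macrophages, with a median of 480 CPM against 233 CPM in microglia. All 16 homeostatic microglia markers were higher in microglia, with a median of 2929 CPM against 149 CPM. Tmem119 stood at 43.6 CPM in macrophages and 3512 CPM in microglia, and Mrc1, the mannose receptor, at 4678 and 2042 CPM. The median of the astrocyte list was 6.92 CPM in macrophages and 6.94 CPM in microglia, and that of the oligodendrocyte list 4.34 and 11.6 CPM. Single members stood higher: the myelin gene Mbp was at 263 CPM in macrophages and 137 CPM in microglia, Cnp at 93.3 and 90.7 CPM, and Slc1a3 at 67.1 CPM in microglia. The medians of the mural cell, endothelial, fibroblast, neuron, monocyte and neutrophil, lymphocyte and dendritic cell lists were 1.75 CPM or less in both.

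**Figure D1:**
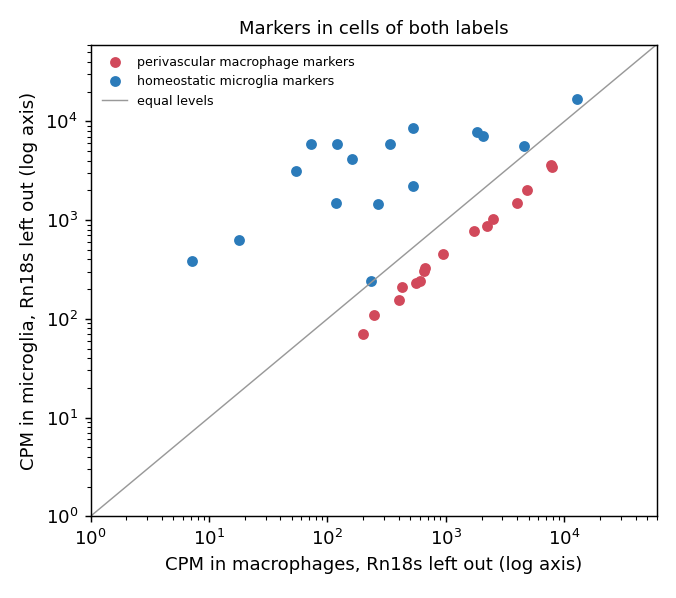
Level of each marker gene in macrophages (horizontal, CPM with Rn18s left out of the total, log axis) and in microglia (vertical, same unit), 1 point per gene, for 16 perivascular macrophage markers and 16 homeostatic microglia markers, with the line of equal levels. The perivascular markers lie along a band at 35.3% to 50.0% of their macrophage level, and the homeostatic markers spread widely above the line.

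Xist and the Y-linked genes placed each of the 8 pools in 1 sex, and every genotype held pools of both sexes. The KO pool of plate 060s was male and that of plate 524s female. On plate 524s the KO pool was female and the Het pool male, and on plate 529s the Het pool was female and the WT pool male, so that genotype and sex went together inside both plates. In macrophages Xist stood at 236 CPM in WT, 44.1 CPM in Het and 83.8 CPM in KO, and Ddx3y at 18.0, 47.1 and 27.6 CPM. In microglia Xist stood at 101, 209.8 and 287.5 CPM, and Eif2s3y at 21.5, 44.2 and 28.9 CPM.

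The first comparison asked which genes KO macrophages expressed at another level than WT and Het macrophages. The lectin genes Cd209f and Cd209b were higher in KO: Cd209f stood at 699 CPM (95% interval 689 to 708) against 313 CPM in WT and 154 CPM in Het, and Cd209b at 73.0 CPM (70.1 to 76.0) against 27.8 and 2.93 CPM. Hpse, which encodes the heparan sulfate-cleaving enzyme heparanase, was 4.92-fold above WT and 2.98-fold above Het. Slfn5, of the Schlafen family, was 3.52-fold and 4.10-fold higher. Genes lower in KO included the histone gene H4c4, the transcription factor gene Cebpd, the glycolysis regulator gene Pfkfb3 and the granule proteoglycan gene Srgn. Of 5069 measured genes, 13 were apart above and 26 apart below both controls, and 12 of each are named here. In simulated counts the rule called 33 unchanged genes with spread between cells alone, and 191 with spread between pools added. The 39 genes apart lay between these numbers, so the rule alone does not show that a named gene changed.

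The other genes named as higher in KO macrophages were Tmem198b, Slc39a8, Rad52, Rnf123, Ccz1, Zfp869, Nt5c3 and Gsn. Slc39a8, a zinc transporter, stood at 13.7 CPM in WT, 7.77 CPM in Het and 35.6 CPM in KO. Gsn, the actin-severing protein gelsolin, stood at 36.0, 34.0 and 83.8 CPM. Tmem198b was 3.05-fold above WT and 4.54-fold above Het, and Rad52, a recombination repair gene, 2.55-fold and 3.68-fold. Rnf123, Ccz1, Zfp869 and Nt5c3 lay between 2.09-fold and 2.66-fold above WT and between 2.43-fold and 3.33-fold above Het. Inside plate 524s, the only plate with KO and Het, the rule itself fixed the direction, and the sizes of the log2 ratios were 4.91 for Slfn5, 3.95 for Gsn and 3.19 for Nt5c3, but 0.06 for Rnf123, 0.18 for Tmem198b, 0.33 for Ccz1, 0.67 for Cd209b and 0.74 for Cd209f, while Hpse had 0 counts in Het there. Without plate 530s the log2 ratios over WT were 0.25 for Nt5c3 and 0.26 for Zfp869, without plate 060s that of Cd209b was 0.39, and without plate 056s those over Het were 0.30 for Rnf123, 1.28 for Cd209f and 2.36 for Cd209b. With 1 plate left out, the lowest log2 ratios over Het were 1.24 for Slfn5, 1.12 for Tmem198b and 0.67 for Gsn. Over WT they were 1.02 for Slfn5, 0.71 for Gsn and 0.84 for Slc39a8. Of 9 alternatives that replaced the level, scaling, pseudocount, depth or cells, Rnf123 and Nt5c3 stayed apart in 2, Zfp869 in 4 and Gsn in 5. The most heavily counted single cell supplied 35.1% of the KO counts of Cd209b. In KO of plate 524s alone, the top cell supplied 86.3% of the Cd209b counts and 54.1% of the Cd209f counts. The median cell of that pool held 8.70 CPM of Cd209f, beside 267 CPM in KO of plate 060s and 0 to 76.4 CPM in the control pools. Cd209f and Cd209b both lost their separation without the top cell of each pool, in thinned cells and by the mean of the cells' own CPM. Reads of Cd209 genes can be shared between members of the family, and exons of Slfn5, Rnf123, Tmem198b and Ccz1 overlap other genes, so the source of their counts is uncertain.

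Among genes lower in KO macrophages, H4c4 stood at 14.7 CPM in WT, 37.1 CPM in Het and 2.17 CPM in KO, and is uncertain because histone genes resemble each other. Cebpd stood at 64.0, 49.7 and 15.0 CPM, Pfkfb3 at 28.2, 47.1 and 6.06 CPM, and Srgn at 46.6, 89.6 and 16.2 CPM. Crk, a signalling adaptor, stood at 55.8, 94.6 and 15.8 CPM. Smarcd2, a chromatin remodelling subunit, was 3.53-fold below WT and 10.9-fold below Het, and Slmap 2.49-fold and 11.8-fold below. Pprc1, a transcriptional coactivator, was 6.68-fold and 4.11-fold below, and the metalloprotease gene Adam19 3.94-fold and 2.88-fold below. Cdc16 of the anaphase-promoting complex, the mitochondrial sulfur enzyme gene Ethe1, and Wdr24 were 2.04-fold to 2.78-fold below WT and 4.14-fold to 5.86-fold below Het. Inside plate 524s, where the rule fixed the direction, the log2 ratios ran from -3.97 for Pfkfb3 to -0.81 for Srgn. Without plate 056s the log2 ratios over Het were -0.57 for Srgn, -0.58 for Cdc16, -0.75 for Adam19 and -0.79 for Cebpd, and without plate 524s that of Wdr24 over WT was -0.70. With 1 plate left out, the weakest log2 ratios over Het were -1.19 for Smarcd2, -2.28 for Slmap and -1.21 for Pprc1. Ethe1 stayed apart in 2 and Wdr24 in 5 of the 9 alternatives. Exons of Pprc1, Cebpd, Ethe1 and Adam19 overlap other genes.

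**Figure D2:**
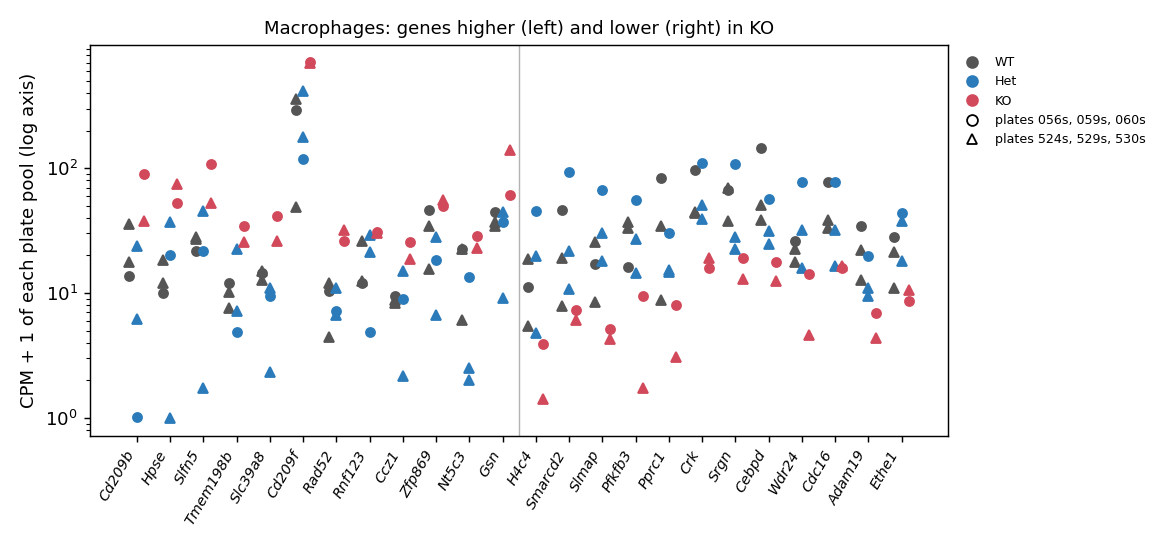
Level of each named gene in macrophages (vertical, CPM + 1, log axis), 1 point per pool of cells of 1 genotype on 1 plate, for genes higher in KO (left) and lower in KO (right). Cd209f lies at 689 and 703 CPM in the KO pools and between 47.9 and 412 CPM in the control pools, and Crk at 14.8 and 18.0 CPM against 38.2 to 109 CPM.

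These gene counts were small beside the spread between plates. Among the 27 other choices of 2 pools, 22 gave at least as many genes against the remaining pools as the 60 that the KO pools gave, with a median of 115 and a highest count of 1264 for WT of plate 059s with Het of plate 056s. That pair took both pools from plates 056s, 059s and 060s, and others took both from plates 524s, 529s and 530s. The KO pair took 1 from each. With Rn18s left out of the total, 18 of the 27 gave at least as many as the 71 of the KO pools, and the highest count was 349, for another pair. Without plate 060s, 64 genes were higher and 600 lower, without plate 524s 77 and 70, without plate 056s 20 and 19, and without plate 059s 19 and 16, and the lower genes numbered 65 without plate 529s and 55 without plate 530s. Fewer pools make the rule easier to meet by construction. The median log2 ratio of all measured genes was 0.00 for KO over WT but -0.50 for KO over Het, and -0.05 and -0.09 with Rn18s left out of the total, where 18 genes were higher and 34 lower and 31 genes were shared with the first count. Thinned cells kept 6 of the 13 higher and 4 of the 26 lower genes, and removal of each gene's top cell in each pool kept 6 and 5.

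Of the gene lists with a median, sex-linked genes aside, interferon response genes had the highest and immediate early genes the lowest medians in KO macrophages over both controls, but 0 of 15 and 0 of 17 measured members were apart at the 1.5-fold limit. The interferon list had a median log2 ratio of 1.27 over WT and 1.05 over Het, both above the 10000 random lists (percentile 100), and 13 of its 15 measured members lay above the random median against WT and 15 against Het. Oasl2, an antiviral sensor gene, stood at 107 CPM in WT, 76.5 CPM in Het and 178 CPM in KO, and Bst2, which encodes tetherin, at 177, 236 and 191 CPM. The immediate early and dissociation stress list had medians of -1.44 and -1.57 (percentile 0 for both), and its member Zfp36 stood at 154, 195 and 64.9 CPM and Dnajb1 at 72.2, 155 and 60.3 CPM. Both differences were larger on plates 056s, 059s and 060s, where the interferon median was 1.33 over WT and 1.71 over Het and the immediate early median -2.19 and -2.05. Each of these plates held 1 genotype, Het, WT and KO in that order, so plate and genotype could not be told apart there. On plates 524s, 529s and 530s the interferon medians were -0.28 and -1.12 and the immediate early medians -0.54 and 0.05. Without plate 060s the interferon medians were -0.32 and -0.71, without plate 059s the immediate early median over WT was -0.65, and without plate 056s that over Het was -0.08. Without the 10% of cells of each pool with the highest interferon share, a setting chosen after seeing the data, the interferon medians were 0.42 over WT and 0.64 over Het. Inside plate 524s the interferon median for KO over Het was 0.77 and the immediate early median 0.14, beside 0.02 for all genes.

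Inflammatory genes had medians of -0.45 over WT (percentile 0.78) and -1.35 over Het (0.02), with Cd14 at log2 ratios of -0.35 and -1.31 and the chemokine gene Ccl7 at -0.34 and -3.31, but the median was 0.08 over WT without plate 059s and 0.49 over Het without plate 056s. Disease-associated microglia genes had a median of -0.41 over WT (0.39) and -0.34 over Het (75.6), with Apoe at -0.10 and -0.57 and Ctsb at 0.27 and -0.34, and the median over Het was 0.47 without plate 056s. Oligodendrocyte markers had a median of -0.97 over WT (0.16), which was -0.37 without plate 059s, and 0.32 over Het, which was -0.48 without plate 056s, and Mobp, a myelin gene, was apart at the 1.5-fold limit, at 31.3 CPM in WT, 21.8 CPM in Het and 13.0 CPM in KO. Antigen presentation genes had medians of 0.17 over WT (82.2) and 0.15 over Het (99.0), with H2-D1 at 0.34 and -0.17 and B2m at -0.18 and -1.04. Homeostatic microglia markers had medians of 0.01 (34.9) and 0.03 (99.7), with Csf1r at 0.33 and 0.02 and Fcrls at 0.24 and -0.32. Ratios over Het are read beside random lists, whose median over Het was -0.44 for the interferon list. That reference covers all plates, and none is given for medians without plate 056s.

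Perivascular macrophage markers had medians of -0.01 over WT (percentile 13.4) and -0.60 over Het (7.87), and of their 16 members Cd209f was apart. The Notch pathway list had medians of -0.02 (40.2) and -0.46 (46.6), with the gamma-secretase gene Ncstn at -0.02 and -0.54 and Adam17 at 0.48 and 0.35. Lysosome genes had medians of 0.24 (96.8) and -0.34 (77.3), with Grn at 0.45 and 0.26, and phagocytosis and scavenger receptors 0.20 (91.7) and -0.59 (12.2), with Mrc1 at 0.40 and -0.60. Complement genes had medians of -0.04 and -0.51, with C1qb at -0.15 and -0.39, cholesterol and lipid genes -0.05 and -0.23, with Abca1 at 0.06 and -0.24, and iron genes 0.05 and -0.64, with Fth1 at -0.59 and -1.15. Growth factors and matrix genes had medians of 0.14 and -0.51, with Tgfbi at 0.46 and 0.43, oxidative phosphorylation -0.04 and -0.46, with Atp5b at -0.07 and -0.47, and cell cycle -0.01 and -0.50, with Tubb5 at -0.07 and -0.16. Astrocyte markers had medians of -0.34 and -0.55, with Gfap at -0.51 and -0.42, ribosomal proteins -0.23 and -0.25, with Rpl4 at -0.26 and -0.40, and sex-linked genes 1.41 and -0.53. Mitochondrial genes had medians of -0.13 over WT (7.34) and -0.71 over Het (5.79), with mt-Co1 at 0.02 over WT and -0.70 over Het. Without plate 056s the medians over Het of all lists of this paragraph except the astrocyte list lay above 0. They ran from 0.13 for complement genes to 0.65 for growth factors and matrix genes, with 1.23 for sex-linked genes. Rn18s took 17.2% of counts in the Het pool of plate 056s, beside 53.8% and 54.9% in the other Het pools. Leaving that pool out raises ratios over Het of genes at large through the total. No median of all genes is given for this setting, so medians above 0 do not single out these lists. Without plate 060s the medians over WT were -0.42 for phagocytosis receptors, -0.43 for growth factors and matrix genes and -2.42 for sex-linked genes, and without plate 059s that of astrocyte markers was 0.61. The mural cell, endothelial, fibroblast, lymphocyte and dendritic cell lists had 1 measured member each, and the neuron and the monocyte and neutrophil lists 2 each, and were given no median. Exons of Adam17, Atp5a1, Csf1r, Ctsb, Grn, Mobp, Ncstn, Rpl4, Stab1, Xist, Zfp36 and mt-Co1 overlap other genes, and Czib, Dipk1a, H4c4 and Kifbp could not be looked up under those names.

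**Figure D3:**
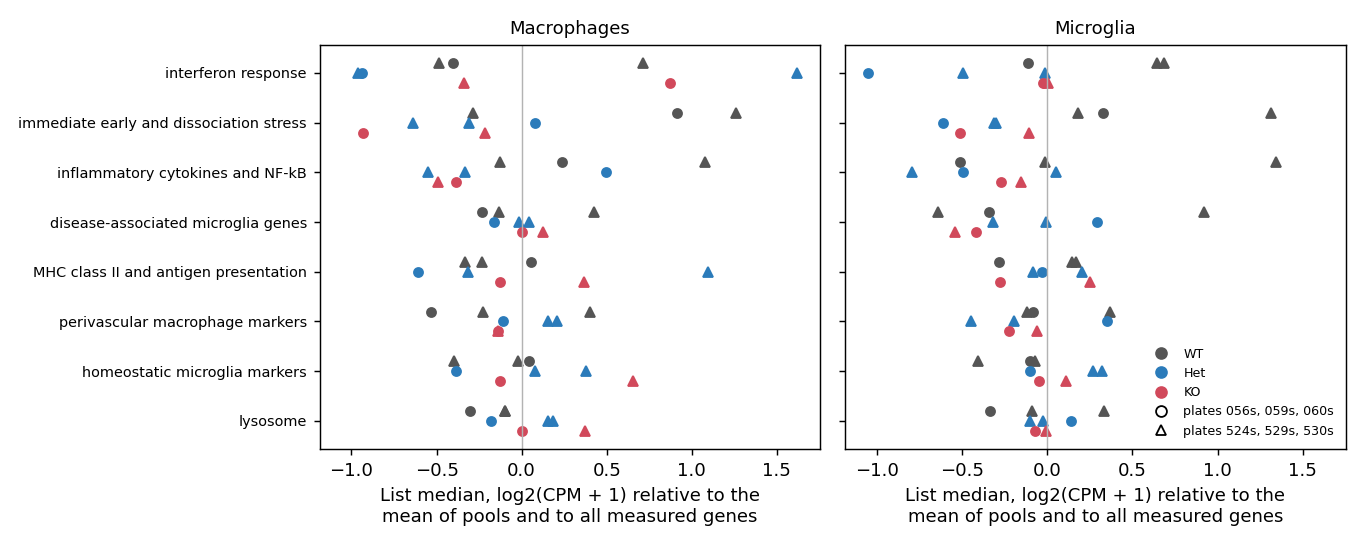
Median log2 level of each of 8 gene lists in each pool (horizontal, log2 of CPM + 1 relative to the mean of the pools and to all measured genes), for macrophages and microglia, 1 point per pool. In macrophages the interferon list lies at 0.87 in KO of plate 060s and -0.34 in KO of plate 524s, and Het of plate 529s lies highest at 1.62.

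The comparison of Het with WT macrophages asked what loss of 1 copy of Notch3 went with. Emc9 was 6.74-fold higher in Het, at 33.1 CPM against 4.06 CPM, and Czib 6.17-fold, at 119 against 18.4 CPM. Stn1, a telomere maintenance gene, was 4.50-fold higher, the anion transporter gene Slc26a6 4.46-fold and Gucd1 4.40-fold. Mad1l1, of the spindle checkpoint, was 9.50-fold lower in Het, at 3.50 CPM against 41.8 CPM, and Smg5, of nonsense-mediated decay, 7.46-fold lower. The annexin gene Anxa4 stood at 14.3 CPM in Het against 63.3 CPM in WT, and the ribosome biogenesis gene Tcof1 was 3.55-fold and the ubiquitin ligase gene Fbxw11 3.54-fold lower. Inside plate 529s, the only plate with Het and WT, the rule fixed the direction, and the log2 ratios were 2.25 for Gucd1, 1.24 for Czib, 1.10 for Slc26a6 and 0.98 for Emc9, and -4.93 for Mad1l1, -2.82 for Fbxw11, -1.55 for Tcof1, -1.18 for Smg5 and -0.63 for Anxa4, while Stn1 had 0 counts in WT there. Without plate 056s the log2 ratios were 1.35 for Czib, 1.33 for Slc26a6, 0.97 for Emc9, 0.69 for Gucd1 and -1.32 for Anxa4. Exons of Emc9, Gucd1, Stn1, Mad1l1 and Anxa4 overlap other genes.

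Inflammatory genes had a median of 1.13 in Het over WT macrophages (percentile 99.9), but their member Nlrp3 was apart below, at 8.96 CPM against 24.2 CPM. The inflammatory median was -1.53 inside plate 529s, where all genes had -0.06. Oligodendrocyte markers had a median of -1.23 (0.03), but it was 0.56 on plates 524s, 529s and 530s, and of the Het pools that of plate 056s alone was low, at -1.62 relative to the mean of the pools, beside 0.35 and 0.16. Of 4950 measured genes 62 were higher and 21 lower, a higher share of 74.7%, and with Rn18s left out of the total 42 were higher and 83 lower, a higher share of 33.6%, while the median shift of all genes went from 0.50 to 0.03. Without plates 056s, 059s, 524s, 529s and 530s in turn, the higher genes numbered 46, 295, 190, 317 and 85 and the lower genes 470, 20, 44, 87 and 128.

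In microglia, the comparison of KO with both controls found few genes apart. The zinc finger gene Zbtb49 stood at 5.25 CPM in WT, 6.76 CPM in Het and 27.9 CPM (95% interval 26.2 to 29.7) in KO. Thbd, the anticoagulant receptor thrombomodulin, stood at 15.2, 15.5 and 35.8 CPM, and Gprc5c, an orphan receptor, at 46.9, 51.2 and 107 CPM. The diphthamide synthesis gene Dph7 was 3.13-fold above WT and 2.36-fold above Het, and Zfp639 2.98-fold and 4.84-fold. Genes lower in KO included Psmd6 of the proteasome, at 58.0 CPM in WT, 54.3 CPM in Het and 18.7 CPM in KO, Ppp2r5d, a phosphatase subunit, at 34.2, 42.7 and 9.08 CPM, and Wdr7 at 54.4, 40.3 and 16.4 CPM. Of 5604 measured genes 7 were higher and 19 lower. In simulated counts the rule called 47 unchanged genes with spread between cells alone, and 202 with spread between pools added. Both numbers exceed the 26 genes apart, so the rule alone does not show that a named gene changed.

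Smg6, which cleaves RNA in nonsense-mediated decay, was higher in KO microglia, at 24.7 CPM against 11.2 CPM in WT and 9.04 CPM in Het. Ap5s1 was 2.25-fold and 2.19-fold higher. Epb41l1, a membrane skeleton gene, was 5.76-fold below WT and 11.0-fold below Het, the adhesion gene Sdk1 4.66-fold and 5.91-fold, and the amino acid transporter gene Slc36a4 3.78-fold and 4.29-fold. Eif2b5, of translation initiation, was 3.95-fold and 2.82-fold below, and Mrps30, of the mitochondrial ribosome, 2.61-fold and 3.76-fold. Etfrf1, Dipk1a and the RNA helicase gene Ddx52 were 2.22-fold to 2.90-fold below WT and 3.05-fold to 5.96-fold below Het. Inside plate 524s, where the rule fixed the direction, the log2 ratios were 2.12 for Zbtb49, -3.85 for Epb41l1 and -1.90 for Ppp2r5d, but 0.05 for Ap5s1, 0.13 for Gprc5c, -0.07 for Psmd6 and -0.03 for Ddx52. Without plate 056s the log2 ratios over Het were -0.28 for Psmd6, -0.47 for Ddx52 and 0.57 for Ap5s1, without plate 059s those over WT were -0.49 for Psmd6, -0.66 for Ddx52 and -0.91 for Wdr7, and without plate 524s that of Zfp639 over WT was 0.58. With 1 plate left out, the weakest log2 ratios over Het were -0.92 for Slc36a4, -0.86 for Etfrf1, -0.95 for Ppp2r5d and -2.28 for Epb41l1. Over WT they were -0.88 for Dipk1a, -0.81 for Mrps30 and -1.44 for Sdk1. Of the 9 alternatives, Ap5s1 and Ddx52 stayed apart in 2, Mrps30 in 3 and Zfp639 and Gprc5c in 4. Exons of Smg6, Zfp639, Etfrf1, Ppp2r5d, Mrps30 and Wdr7 overlap other genes.

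**Figure D4:**
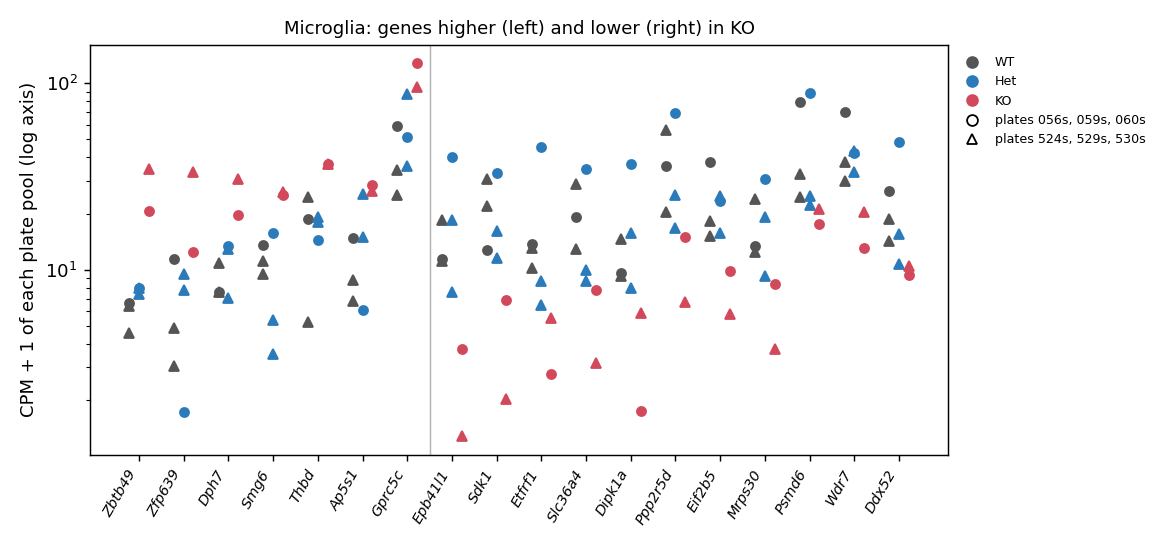
Level of each named gene in microglia (vertical, CPM + 1, log axis), 1 point per pool of cells of 1 genotype on 1 plate, for genes higher in KO (left) and lower in KO (right). Zbtb49 lies between 19.6 and 33.6 CPM in the KO pools and between 3.57 and 6.95 CPM in the control pools, and Psmd6 between 16.6 and 20.1 CPM against 21.1 to 87.9 CPM.

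All 27 other choices of 2 pools of microglia gave at least as many genes as the 39 that the KO pools gave against the remaining pools, with a median of 157 and a highest count of 1182. With Rn18s left out of the total, 26 of the 27 gave at least as many as the 86 of the KO pools, and the highest count was 441. Without plates 056s, 059s, 060s, 524s, 529s and 530s in turn, the higher genes numbered 24, 40, 41, 96, 14 and 8 and the lower genes 10, 15, 200, 101, 65 and 28. The median log2 ratio of all measured genes was -0.20 over both WT and Het, and -0.04 and 0.00 with Rn18s left out of the total, where 22 genes were higher and 32 lower, 19 genes were shared with the first count, and the higher share went from 26.9% to 40.7%.

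Among the lists, disease-associated microglia genes had medians of -0.70 over WT (percentile 0.01) and -0.61 over Het (0.08) in KO microglia, with Apoe, a lipid carrier, at -0.58 and -0.47, but no member was apart. The median over WT was -0.11 without plate 530s and that over Het 0.13 without plate 056s, and WT of plate 529s, at -0.64 relative to the mean of the pools, lay below both KO pools, at -0.42 and -0.54. On plates 056s, 059s and 060s these medians were -0.18 and -1.12, and on plates 524s, 529s and 530s -0.97 and -0.16, while inside plate 524s the median was 0.23 for KO over Het beside 0.28 for all genes. Immediate early genes had medians of -0.96 over WT (0) and 0.06 over Het (90.4), with Btg2 at -0.66 and -0.11, and inflammatory genes -1.13 (0.01) and -0.30 (26.9), with Cd14 at -0.22 and -0.50, where the inflammatory medians were -0.17 over WT without plate 529s and 0.19 over Het without plate 056s. Interferon genes had medians of -0.26 over WT (40.2) and 0.35 over Het (99.6), with Oasl2 at 0.33 and 0.86, and the median over Het was -0.09 without plate 060s. In the antigen presentation list, with medians of -0.30 and -0.18, the peptide transporter gene Tap1 was apart at the 1.5-fold limit, at 81.8 CPM in WT, 54.0 CPM in Het and 153 CPM in KO, and its exons overlap Psmb9.

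Perivascular macrophage markers had medians of -0.27 over WT (percentile 7.71) and -0.51 over Het (0.05) in KO microglia, with Mrc1 at -0.13 and -0.29. These markers may come from macrophage RNA in the wells of microglia, so their ratios need not be expression by microglia. Their mean sum in microglia was 32.1% to 47.3% of that in macrophages of the same pool. Other genes high in macrophages, such as Apoe, are open to the same reading. Complement genes had medians of -0.25 (13.2) and -0.47 (0.75), with C1qa at -0.36 and -0.40. On plates 524s, 529s and 530s the median of the perivascular markers over Het was 0.51, beside -1.02 on the other plates. Homeostatic markers had medians of 0.02 (94.3) and -0.19 (47.6), with Csf1r at 0.11 and 0.00, and cholesterol and lipid genes -0.45 (1.89) and -0.17 (49.9), with Lrp1 at -0.35 and 0.01. Iron genes had medians of -0.22 and -0.42, with Fth1 at -0.68 and -0.60, lysosome genes -0.18 and -0.30, with Lgmn at -0.04 and -0.30, and phagocytosis genes -0.15 and -0.26, with Stab1 at 0.26 and 0.14. The Notch pathway list had medians of -0.24 (28.7) and -0.06 (77.8), with Ncstn at 0.06 and -0.02. Growth factor and matrix genes had medians of -0.14 and -0.31, with Tgfbr2 at -0.13 and 0.14, oxidative phosphorylation -0.28 and -0.25, with Atp5a1 at -0.18 and -0.33, and cell cycle genes -0.59 and 0.26, with Mcm3 at -0.25 and 0.06. Ribosomal proteins had medians of -0.22 and 0.00, mitochondrial genes -0.07 and -0.19, and sex-linked genes 0.41 and -0.59. Endothelial markers had medians of 0.70 and 0.32, with Pecam1 at 0.70 and 0.32, astrocyte markers -0.50 and 0.15, with Slc1a3 at 1.07 and 0.15, oligodendrocyte markers -0.48 and 0.15, with Mbp at -0.32 and 0.03, and monocyte and neutrophil markers -0.54 and -2.37, with S100a9 at -0.11 and -2.79. Without plate 056s the medians over Het of all lists of this paragraph except the monocyte and neutrophil list lay above 0. They ran from 0.04 for complement genes to 0.61 for perivascular markers and 0.70 for oligodendrocyte markers, with 1.40 for sex-linked genes. Rn18s took 16.4% of counts in the Het microglia of plate 056s, beside 56.4% in each other Het pool. Leaving plate 056s out thus raises ratios over Het of genes at large. No median of all genes is given for this setting, so medians above 0 do not single out these lists. Without plate 059s the medians over WT were 0.52 for growth factor and matrix genes, 0.69 for astrocyte and 0.82 for oligodendrocyte markers, and without plate 524s those over Het were -0.63 for astrocyte and -0.29 for endothelial markers. The mural cell, fibroblast and lymphocyte lists had 2 measured members each and the neuron and dendritic cell lists 1 each, and were given no median.

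In the comparison of Het with WT microglia, 2 of 16 measured immediate early genes and 2 of 15 interferon genes were apart, all lower in Het. Egr1, an immediate early transcription factor, was 12.7-fold lower, at 1.48 CPM against 30.4 CPM, and Irf7, a regulator of interferon genes, 4.59-fold lower, at 7.41 against 37.7 CPM. Junb stood at 37.0 CPM in Het and 83.5 CPM in WT, and Ifi204, an interferon-inducible gene, at 17.8 and 48.1 CPM. The list medians were -1.08 for immediate early genes (percentile 0) and -0.57 for interferon genes (0.49), and inside plate 529s -1.90 and -0.33. For the interferon list the pools overlapped, with Het of plate 529s at -0.01 and WT of plate 059s at -0.11 relative to the mean of the pools. Ifrd1 was 9.62-fold, Kifbp 8.13-fold and the semaphorin receptor gene Plxnd1 5.59-fold lower in Het, while Rexo5 was 8.75-fold, Oard1 4.38-fold, Zfp35 3.84-fold, Taf1 3.53-fold and Rbm38 3.47-fold higher. Zbtb46 and the ribosomal gene Rpl8 were also apart below among list members. Inside plate 529s, where the rule fixed the direction, the log2 ratios of the 10 genes named by fold ran from -2.10 for Kifbp to 2.68 for Oard1. Without plate 056s the log2 ratio of Oard1 was 0.90 and that of Rexo5 less than its log2 ratio of 3.13 over all plates. The lowest log2 ratio of Rexo5 with 1 plate left out was 1.501. Without plate 059s the log2 ratios of Rbm38 and Kifbp were 0.99 and -1.96, and without plate 530s that of Plxnd1 was -1.33. Astrocyte markers had a median of -0.996 in Het (percentile 1.31). Monocyte and neutrophil markers, with 3 measured members, had a median of 1.83 (98.9). For Het of plate 056s over WT of plate 059s these medians were -1.81 and -0.29. On plates 524s, 529s and 530s they were 0.07 and 2.37, and inside plate 529s 0.18 and 1.89. Of the pools, WT of plate 530s lay lowest for astrocyte markers, at -1.53 relative to the mean of the pools. Exons of Irf7, Rexo5, Ifrd1 and Rbm38 overlap other genes.

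Of 5455 measured genes, 34 were higher and 81 lower in Het microglia, and with Rn18s left out of the total 98 were higher and 102 lower, so that the higher share went from 29.6% to 49.0%. Without plates 056s, 059s, 524s, 529s and 530s in turn, the higher genes numbered 20, 427, 122, 222 and 57 and the lower genes 474, 84, 130, 242 and 255.

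With all counts in the total, no gene was apart in KO in both cell types among the 4620 genes measured in both, where 8 and 2 of the genes were higher and 19 and 8 lower in macrophages and microglia. Between Het and WT, Fbxw11 was lower in Het in both cell types, and Smg9 was higher in Het macrophages and lower in Het microglia.

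Macrophages were 72.8% of WT cells (exact 95% interval 67.2% to 77.8%), 54.7% of Het cells (45.7% to 63.5%) and 60.4% of KO cells (53.2% to 67.3%). Plates of 1 genotype differed as much: the share was 67.6% in KO of plate 060s and 40.4% in KO of plate 524s, and it ran from 51.6% to 87.3% over the WT pools and from 40.4% to 70.0% over the Het pools. Such shares can be set by the sort gate and by filters applied before deposit.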

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

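The tests in this part were chosen only after the results were seen. The interferon response list had a median of 1.27 in KO over WT macrophages, with 0 of 15 members apart and Het of plate 529s, not a KO pool, highest. The Rn18s share of the total did not account for it, since the median was 1.23 with Rn18s left out. Whether a few cells with high interferon counts carry part of it was not settled. The median did not fall when each gene lost its top cell in each pool, at 1.39. It was 0.97, 0.42 and 0.29 when each pool lost the 5%, 10% or 20% of cells with the highest interferon share. Those cells were chosen by the list itself, which lowers its level in every pool, and no other list was treated so. Another candidate explanation is KO plate 060s alone. On plates 524s, 529s and 530s the list lay at -0.572 log2 relative to all genes, averaged over WT and Het. Inside plate 524s, however, KO stood 0.77 above Het. That average cannot show it, because it also rests on high controls of plate 529s. The summed list stood at 1111 CPM in WT and 1597 CPM in Het there, and 1 of those 19 Het macrophages supplied 51.4% of the Het sum. It stood at 631 CPM in KO of plate 524s, above 557 CPM in WT of plate 530s and 407 CPM in Het of plate 524s. That was below 919 CPM in WT of plate 059s and 797 CPM in Het of plate 056s. The median cell, Rn18s left out, held 1236 CPM in KO of plate 524s and 1124 CPM in KO of plate 060s. It held 1964 and 1513 CPM in WT and Het of plate 529s, and from 607 to 768 CPM in the other control pools. Mx1 stood at 156 CPM in KO of plate 060s and 1.34 CPM in KO of plate 524s. Loss of Notch3 and the sex of the animals stay open and untested, although sex alone did not order the pools, which relative to their mean ran from -0.96 to 0.87 in males and from -0.48 to 1.62 in females.

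Cd209f and Cd209b were higher in KO macrophages. The Rn18s share of the total did not account for Cd209f, whose smaller log2 ratio was 1.11 with Rn18s left out. The cell with the most counts of the gene in each pool may carry the separation of KO of plate 524s. Without that cell, KO of plate 524s stood at 0.254 of the highest control pool for Cd209b and at 0.994 for Cd209f. The removal weighed more on its 21 cells than on the 138 of that control pool, WT of plate 530s. KO of plate 060s stayed above every control pool, at 575 CPM for Cd209f and 52.1 CPM for Cd209b, beside 318 and 19.8 CPM. Spread between plate pools of any genotype may also carry the separation, but was not tested for these genes. By the same rule, 22 of the 27 other choices of 2 pools gave as many genes. That count covers all genes and cannot decide for Cd209f and Cd209b. An effect of Notch3 loss stays open and untested.

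Cells labelled microglia held perivascular macrophage markers at 35.3% to 50.0% of the macrophage level. Reads swapped between wells were argued against by Xist, which in male cells of plates 524s and 529s reached 0.249% of its level in female cells. Macrophages labelled as microglia were argued against by the share of 54.9% of microglia with a marker sum between the low and the macrophage range. That does not cover the 67 of 215 that lay within the macrophage range. The sum of homeostatic markers had a 5th percentile of 43445 CPM in microglia, above the 95th percentile of 37935 CPM in macrophages. The labels were probably made from the same counts, so that separation cannot decide for these 67 cells. Macrophage RNA in the wells of microglia may account for it, since among genes of at least 200 CPM in macrophages the lowest ratio of microglia to macrophages was 0.324, although at a floor of 100 CPM 7 of 1713 genes lay under 0.3, with Ccl2 lowest at 0.184. Wells with 2 cells and a macrophage program expressed by these microglia stay open, and no biological explanation was tested.

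Cells of type 7 entered no comparison between genotypes. Of 12 comparisons of their highest or lowest cell with the nearest other, 2 stood far out, both for the highest total counts. The limits pass about 1 in 20 groups by chance only where values are normally distributed. Total counts of these cells ran from 3742 to 688942 with a median of 47582, so that rate cannot be assumed here. The deepest of 4 WT cells of type 7 held 298941 counts and the next 29715. The deepest of 6 KO cells of type 7 held 688942 counts and the next 137247. Vmn1r13 had a mean of 4562 CPM and a median of 1080 CPM in type 7 cells, some of which held as few as 3742 counts, and a mean of at most 178 CPM in the other types. Ndrg2 had a mean of 802 CPM in type 7 cells and at most 29.6 CPM in the other types.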

How the results depend on the processing

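No paired analysis was possible because the labels name no animal, numbers given in accession order name cells only, no pair of genotypes shared more than 1 plate, and no result came from a test. Leaving Rn18s out of the total and using plates 056s, 059s and 060s or plates 524s, 529s and 530s alone were chosen after seeing the data. Values follow for genes higher and lower in KO macrophages (13 and 26), higher and lower in Het macrophages (62 and 21), higher and lower in KO microglia (7 and 19) and higher and lower in Het microglia (34 and 81), naming only counts that went beyond 1.5 times.

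At 1.5-fold the counts were 26, 67, 101, 49, 53, 33, 54 and 142 in that order, and at a floor of 50 CPM 6, 10, 30, 6, 1, 3, 10 and 24. A floor of 5 CPM gave 38 lower in Het macrophages, 14 higher and 34 lower in KO microglia and 62 higher in Het microglia. A detection limit of 10% of cells gave 20 higher in KO macrophages and 40 lower in Het macrophages, and no limit gave 20 and 40, and 11 higher in KO microglia. Looser or stricter limits admit more or fewer genes by construction.

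WT alone as control gave 45 and 70 in KO macrophages and 56 and 105 in KO microglia, and Het alone 55 and 168, and 103 and 69. Inside single plates the counts were 803, 822, 617, 718, 799, 362, 462 and 910. Plates 056s, 059s and 060s alone gave 68, 661, 827, 631, 80, 599, 1054 and 642, and plates 524s, 529s and 530s alone gave 186, 318, 123, 310, 206, 67, 168 and 272. Leaving out each plate in turn gave ranges of 11 to 77, 16 to 600, 46 to 317, 20 to 470, 8 to 96, 10 to 200, 20 to 427 and 81 to 474. Fewer pools make the rule easier to meet by construction.

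Without each gene's top cell in each pool, which takes a larger share from small pools, 6 were lower in KO macrophages, 7 higher and 77 lower in Het macrophages, and 22 higher and 2 lower in KO microglia. TMM factors gave 55 lower in Het macrophages, 19 higher in KO microglia and 82 higher in Het microglia, DESeq2 factors 44, 14 and 78, and Rn18s left out of the total 83, 22 and 98, with 32 lower in KO microglia. The mean of pools gave 46 lower in Het macrophages and 25 higher in KO microglia. The mean of the cells' own CPM gave 16 lower in KO macrophages, 31 higher in Het macrophages, 9 lower in KO microglia and 22 higher in Het microglia, and turned the log2 ratio of Wdr24 in KO over WT macrophages from -1.03 to 0.061. A pseudocount of 5 CPM gave 13 lower in KO macrophages and 4 higher and 10 lower in KO microglia. Thinned cells gave 12 lower in KO macrophages, 29 higher in Het macrophages, 12 higher in KO microglia and 21 higher in Het microglia. Of the genes lower in KO, thinned cells kept 4 of 26 in macrophages and 4 of 19 in microglia, and removal of the top cells kept 5 and 1. Apart from the share that the top cell takes from small pools, the cause was not tested for this paragraph.

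Of the log2 ratios of named genes, 1426 of 1527 moved by less than the spread between pools of a genotype under the alternatives fixed in advance, plate removal apart, and 588 of 636 with 1 plate left out. Many of the 1527 could not move. Other floors, detection or fold limits, and WT or Het alone as control, leave these ratios unchanged by construction. Of the list medians, 337 of 616 and 325 of 528 moved by less than the spread of random lists. With the settings chosen after seeing the data, 256 of 318 ratios and 88 of 264 medians did. Tmem198b and Slc39a8 in KO macrophages, Zbtb49 in KO microglia, Tcof1 and Fbxw11 in Het macrophages and Zfp35 and Irf7 in Het microglia stayed apart in all 9 alternatives that replaced the level, scaling, pseudocount, depth or cells and used all pools. Depth limits genes under 20 CPM, and thinning to 107829 counts per macrophage and 148142 per microglial cell left out 31 and 12 KO cells.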

Other observations

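The genes in this part were singled out only after their values were seen. Within the interferon and immediate early lists, single plates of controls also stood apart. In macrophages Ifit2, an interferon-induced gene, stood at 223 CPM in KO of plate 060s, 82.2 CPM in Het of plate 529s, 35.7 CPM in WT of plate 059s and 16.8 CPM in KO of plate 524s. Fos stood at 393 CPM in WT of plate 059s and 376 CPM in WT of plate 529s but 50.4 CPM in WT of plate 530s, beside 11.1 CPM in KO of plate 060s and 45.3 CPM in KO of plate 524s. Cd209g stood at 194 CPM in KO of plate 060s and 36.9 CPM in KO of plate 524s.

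In microglia, the disease-associated genes Spp1 and Gpnmb were carried by a few control pools. Spp1 stood at 1992 CPM in WT of plate 530s and 345 CPM in Het of plate 056s, and Gpnmb at 915 and 250.3 CPM, while in KO Spp1 stood at 4.81 CPM and Gpnmb had 0 counts. Vmn1r13 was seen in 99.8% of all cells, with a median of 543 CPM in the 63 cells with the fewest total counts and 38.6 CPM in the 63 with the most.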
